A study of Mus musculus with 6 samples.

How the data were processed

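Whole kidney RNA from 6 mouse libraries was sequenced, 3 labelled db/db and 3 labelled db/m by their titles and genotype labels. Per the labels' protocols, messenger RNA was enriched on oligo(dT) beads, fragmented and made into strand-specific libraries. Per the submitters' processing notes, fastp, FastQC, HISAT2, SAMtools, StringTie and DESeq2 were used, without versions or roles. The genome build, annotation release and counting settings are not given in the sources used here. The deposited values are whole-number counts per gene symbol, not normalised, in 1 table with a column per library. The table held 24434 symbols, of which 23641 were found in the RefSeq gene table of GRCm38.p6, used only for names, and 729 had no count in any library. All 6 columns were assigned to libraries by their names, in which db with a number stands for the db/db title with that number. Across libraries, counts of 2 occurred 4164 times and counts of 1 occurred 1318 times, so 1 sequenced fragment may have been counted more than once, and counting intervals, which cover counting error only, may be too narrow.

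Total counts were 25937756, 35931140 and 27694351 for db/m replicates 1 to 3 and 27023129, 28038542 and 29868789 for db/db replicates 1 to 3. The upper limit that a count of 0 allows, taken as 3 counts, was 0.083 to 0.116 CPM of the total. Mitochondrially encoded genes took 9.90% to 12.9% of the counts, and the 20 most abundant genes 16.4% to 21.8%. Libraries of the same group differed far beyond sampling noise (chi-square per degree of freedom 17.2 to 64.8), so each was kept as a replicate.

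Genes with low counts were removed with filterByExpr, which left 16373. Libraries were scaled with TMM factors (0.901 to 1.122), and groups were compared with the edgeR quasi-likelihood test (glmQLFit and glmQLFTest, edgeR 4.0.16, R 4.3.3) with no covariates and Benjamini-Hochberg adjustment. An adjusted p below 0.05 counted as a call. CPM values are counts scaled by the TMM-scaled library size, means are given with the SD over 3 libraries, and the SE of a log2 fold change is its size divided by the square root of the F statistic. A log2 fold change is positive where the libraries labelled db/db were higher. Principal components used log2 CPM with a prior count of 2.

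Before the data were examined, 50 gene lists of kidney cell types, neighbouring tissues, immune cells and metabolic or stress pathways were fixed from background knowledge, holding 665 symbols of which 658 were in the table. Of these symbols 14 are in more than 1 list. Lists with at least 3 tested members, 48 in all without the sex chromosome check, were tested against all other genes with camera (limma 3.58.1) at a preset correlation of 0.01 and at an estimated correlation. Each list was also tested against no change with fry, which asks another question. Members were also adjusted over the list alone. The rule for named genes was fixed at the same time: adjusted p below 0.05, average log2 CPM of at least 2, no overlap between groups and no predicted or clone symbol, taking the 12 largest rises and the 12 largest falls. Lepr, up to 4 members of each list by smallest p (3 in the direction most members moved and 1 in the other) and all members of the contamination and sex lists were added. Some genes that this rule names are not reported here. The members Cyp4a12a, Cyp7b1, Slc7a13 and H2-DMb1 in the report, and H2-K1 and B2m in the closing section, were named after their values were seen. Members of the adipocyte, adrenal, urothelial, muscle, red cell and sex lists are given as levels without tests, and the repeats under other settings leave them out, which was decided after some had changed direction there.

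The procedure was tested on simulated counts for db/db against db/m. These used the mean of each gene over all 6 libraries and the TMM-scaled library sizes. Dispersions followed the fitted trend with abundance, so genes that vary more than the trend were not represented. The rates below may therefore differ in the real data. Of 16043 genes tested there, changes of 1.5, 2, 4 and 8-fold were called in the right direction for 12.8%, 74.0%, 87.8% and 100.0% of changed genes, and 4 of 138 calls (2.9%) were false. A list raised by 1.5-fold was recovered as the 1 list called. Genes were drawn independently there, so this could not show how correlation between genes affects list calls.

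Alternatives fixed before the data were examined were DESeq2 size factors, upper quartile and total count scaling in edgeR, the DESeq2 1.42.0 Wald test, limma-voom, no filter and a stricter filter on low counts (at least 1 CPM and 10 counts in 3 libraries), mitochondrial genes left out, the replicate number as a block, and each library left out in turn. Leaving out db/m replicate 3 together with db/db replicate 3 was added after the data were seen. All 10 divisions of the 6 libraries into 3 and 3 were run with the same test. Groups of 3 were too small for an outlier test. Tables and plots were made with Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.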

Results

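The series measured polyadenylated RNA in whole kidneys of mice on normal chow by strand-specific RNA sequencing. It held 6 libraries, 3 labelled db/db and 3 labelled db/m. The db allele disrupts the leptin receptor, and animals with a pair of db alleles become obese and diabetic, whereas db/m animals serve as lean controls. The design text names db/db as the diabetic model, so the comparison asks which kidney transcripts differed between the diabetic and control genotypes. Total counts ranged from 25937756 in db/m replicate 1 to 35931140 in db/m replicate 2, and each library had counts for 19262 to 20874 of the 24434 gene symbols. The labels do not say whether each library came from a separate animal, so p-values measure the spread between these libraries. Sex, age and strain were not given in the sources used here, nor was a genome build, so genes are identified by the symbols in the deposited table and no coordinates are given.

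The gene-level counts gave only a partial check of the genotype labels. Lepr, which encodes the leptin receptor, stood at 4.45 ± 1.68 CPM in the libraries labelled db/db and 3.01 ± 0.566 CPM in those labelled db/m (SD, n = 3 each), with a log2 fold change of 0.56 (SE 0.33, adjusted p = 0.246). Per library it was 5.66, 2.54 and 5.15 CPM under the db/db label and 2.94, 2.48 and 3.61 CPM under the db/m label. The db allele alters splicing of the long receptor form, which a count summed over the gene need not show. This check did not settle the genotypes, and groups are named below by their labels. All 6 libraries had the pattern of male tissue, with Xist at 0.335 CPM of total counts or less and the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y above 7 CPM in each.

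Of 16373 genes tested, 2151 were higher and 1774 lower in the libraries labelled db/db at an adjusted p below 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg). Among these, 608 were at least 2-fold higher and 672 at least 2-fold lower. The groups did not overlap for 44.6% of tested genes, against 10% by chance for 3 against 3, and the first principal component, with 58.2% of the variance, separated them. The balance of directions depended on the scaling: with total counts only, 1072 genes were higher and 4883 lower, and the median log2 fold change over all genes moved from -0.057 to -0.318. Leaving out db/m replicate 2 left 1395 higher and 851 lower, leaving out db/db replicate 3 left 1374 and 891, and the lower calls came to 1038 without db/db replicate 1 and 994 without db/db replicate 2.

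Most listed genes known to be expressed more in male than in female mouse kidney were higher. Of the 9 male-biased genes, 8 rose in the libraries labelled db/db and 1, Cyp4a12a, stood at 172 ± 55.3 against 90.1 ± 26.4 CPM without passing the test (adjusted p = 0.053). Slco1a1, an organic anion transporter, was at 351 ± 41.5 CPM against 0.278 ± 0.113 CPM, a log2 fold change of 10.33 (SE 0.24, adjusted p = 7.18e-06). Kap, the androgen-regulated kidney protein of the proximal tubule, reached 34970 ± 1718 CPM against 641 ± 658 CPM, with 1400 CPM in db/m replicate 3 and less than 300 CPM in both other db/m libraries. Its log2 fold change of 5.77 (SE 0.78, adjusted p = 0.00296) became 7.07 without db/m replicate 3. Odc1, the first enzyme of polyamine synthesis, was at 2051 ± 376 against 131 ± 42.1 CPM, and the cytochrome P450 gene Cyp4b1 at 5446 ± 358 against 796 ± 204 CPM. All 4 listed female-biased genes fell. The amino acid transporter Slc7a12 was at 1.25 ± 0.517 against 22.5 ± 10.1 CPM, the prolactin receptor Prlr at 10.1 ± 1.78 against 54.7 ± 11.1 CPM, and Cyp4a14 at 129 ± 53.4 against 733 ± 135 CPM. The list medians were 3.97 and -3.07 on the log2 scale, and camera with its preset correlation placed the first above other genes (adjusted p = 3.68e-27) and the second below (adjusted p = 6.97e-09). With an estimated correlation both had adjusted p = 0.078. Adjusted over the list alone, 9 male-biased genes rose and 4 female-biased genes fell.

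**Figure D1:**
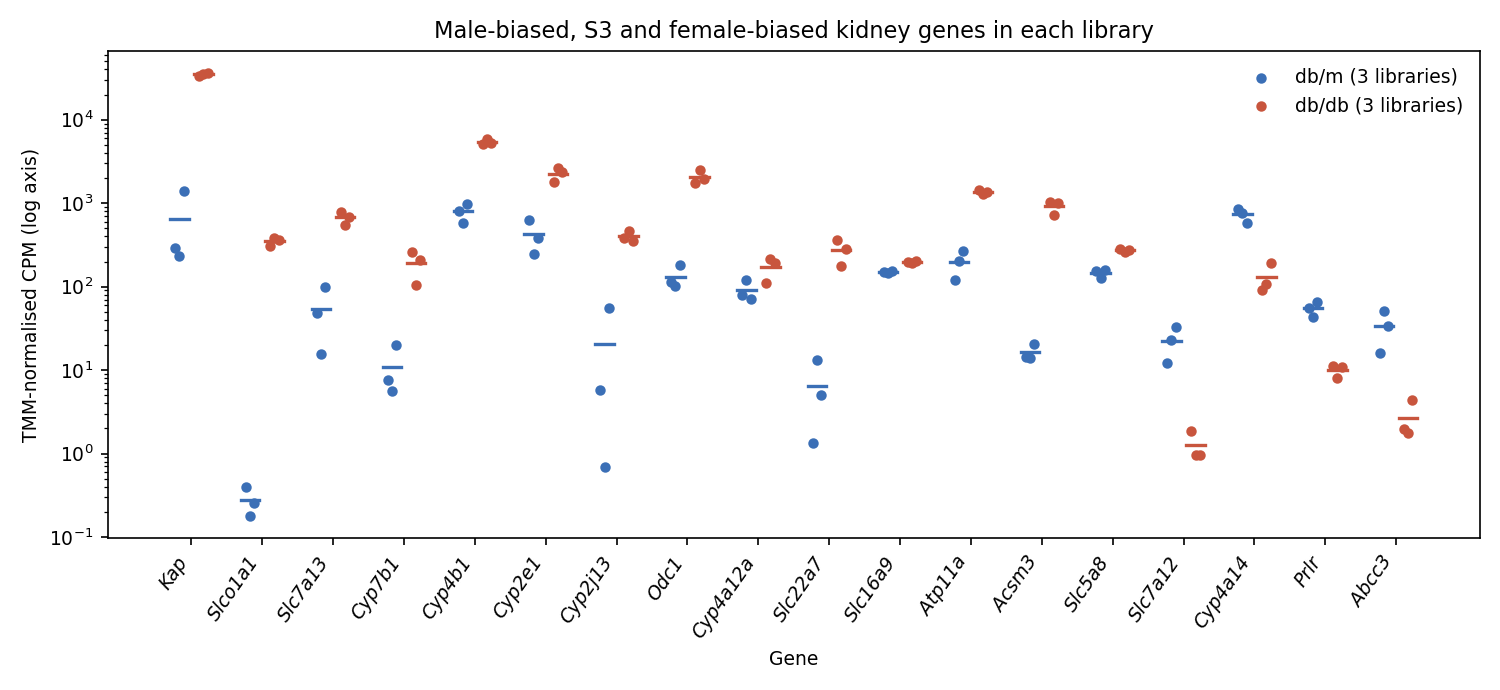
TMM-normalised CPM, on a log axis, of the male-biased, proximal tubule S3 and female-biased list members in each of the 6 libraries; points are libraries and bars are group means. Slco1a1 was at 351 CPM on average in the libraries labelled db/db and 0.278 CPM in those labelled db/m, while Slc7a12 and Prlr lay on the opposite side.

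Markers of the S3 segment, the straight end of the proximal tubule, rose by unequal amounts, from 0.40 to 5.82 on the log2 scale. All 7 were higher in the libraries labelled db/db, over the list alone as well, with a list median of 3.63 (camera adjusted p = 7.34e-15, and adjusted p = 0.177 with an estimated correlation). Acsm3, an acyl-CoA synthetase gene, was at 918 ± 165 against 16.3 ± 3.47 CPM (log2 fold change 5.82, SE 0.23, adjusted p = 3.23e-05). Slc22a7, which encodes an organic anion transporter, was at 274 ± 92.6 against 6.50 ± 6.02 CPM, and its log2 fold change of 5.37 became 6.41 without db/m replicate 2. The flippase gene Atp11a was at 1370 ± 81.8 against 197 ± 74.3 CPM, and Slc5a8, a monocarboxylate transporter gene, was higher by 0.89 on the log2 scale (SE 0.11, adjusted p = 0.00195). The S3 list shares 2 genes with the male-biased list, Cyp7b1 and Slc7a13. Among 15 organic anion and cation transporters 7 rose and 2 fell, or 9 and 2 adjusted over the list alone (camera adjusted p = 2.53e-10, and adjusted p = 0.177 with an estimated correlation). The urate transporter Slc22a12 was at 2445 ± 133 against 586 ± 90.5 CPM and the organic cation transporter Slc22a2 at 408 ± 8.64 against 108 ± 17.9 CPM, whereas the efflux pump Abcc4 was at 23.2 ± 3.19 against 119 ± 30.1 CPM. The transporter list had a median of 0.67 and a mean of 1.44 on the log2 scale. Slco1a1 belongs to this list and to the male-biased one, Slc22a7 is also in the S3 list, and 2 members are also S1 and S2 markers. Markers of the earlier S1 and S2 segments went both ways, with 1 of 15 higher and 4 lower, or 1 and 6 over the list alone. Slc22a6, an organic anion transporter, rose by 1.57 on the log2 scale (SE 0.15), and Gatm, which makes the creatine precursor, fell by 1.29 (SE 0.16). This list did not pass camera (adjusted p = 0.412).

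Cholesterol synthesis genes were higher in part. Of 20 listed, 8 rose and 0 fell, the same counts as over the list alone, and DESeq2 also called 0 lower (2 were lower at an unadjusted p below 0.05). Hmgcs1, which makes the precursor of mevalonate, was at 501 ± 47.0 against 109 ± 24.6 CPM (log2 fold change 2.20, SE 0.17, adjusted p = 0.000415). Idi1 and Mvd, later enzymes of the mevalonate pathway, were higher by 2.37 (SE 0.25) and 1.13 (SE 0.12) on the log2 scale, while Lss had -0.34 (SE 0.13, adjusted p = 0.101, and 0.0132 with total counts only). With total counts only, 6 members were higher and 2 lower. The list passed camera (adjusted p = 0.000515, and adjusted p = 0.916 with an estimated correlation).

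All 5 genes of ketone body metabolism differed, 4 higher and 1 lower, also over the list alone, with a median of 0.67 and a mean of 0.39 on the log2 scale. Acat1, the mitochondrial thiolase, averaged 1008 against 431 CPM (log2 fold change 1.23, SE 0.09, adjusted p = 0.000333), and Bdh1 and Oxct1, which use ketone bodies, were higher by 1.27 (SE 0.25) and 0.67 (SE 0.13), of which Oxct1 did not pass with total counts only (adjusted p = 0.0564). The list passed camera at adjusted p = 0.021, with adjusted p = 0.392 for an estimated correlation, and did not pass without db/m replicate 3 (adjusted p = 0.0604) or with limma-voom (adjusted p = 0.0501).

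Genes of fatty acid oxidation moved in both directions, with 12 of 28 higher and 5 lower, or 15 and 6 over the list alone. Ehhadh, a peroxisomal bifunctional enzyme, was higher by 1.18 (SE 0.11), Angptl4, a secreted inhibitor of lipoprotein lipase, by 1.17 (SE 0.13), and Cpt2, which brings acyl groups into mitochondria, by 0.75 (SE 0.10), while the lower members included Cyp4a14. Camera gave adjusted p = 0.0338, and adjusted p = 0.916 with an estimated correlation. The list's call ended with total counts only (adjusted p = 0.0547), with the stricter filter (adjusted p = 0.0612), without db/m replicate 3 (adjusted p = 0.153) and without db/db replicate 3 (adjusted p = 0.144). Those 2 libraries also held the most adipocyte RNA, with Adipoq at 13.6 and 19.2 CPM against 1.34 CPM or less elsewhere.

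Mitochondrially encoded transcripts were modestly higher, with 5 of 13 called and 8 over the list alone, and 0 lower by edgeR or DESeq2 or at an unadjusted p below 0.05. ND3, a subunit of respiratory complex I, was at 1248 ± 117 against 783 ± 81.5 CPM (log2 fold change 0.67, SE 0.12, adjusted p = 0.00785). The list passed camera at adjusted p = 0.0043, with adjusted p = 0.916 for an estimated correlation. With total counts only its median was 0.20 instead of 0.45 and 2 members were called (camera adjusted p = 0.0104). The mitochondrial share of total counts overlapped between labels, at 9.90% to 12.9% under db/m and 11.7% to 12.9% under db/db. The members called came to 1 without db/m replicate 2, db/db replicate 1 or db/db replicate 3, 2 without db/m replicate 3 and 10 without db/m replicate 1. Of 30 nuclear encoded oxidative phosphorylation genes, 5 rose and 0 fell in edgeR, 0 fell in DESeq2 and 0 were lower at an unadjusted p below 0.05. Ndufa4 and Ndufa1 were higher by 0.72 (SE 0.10) and 0.73 (SE 0.14) on the log2 scale. The nuclear list passed camera (adjusted p = 0.0124, and adjusted p = 0.916 with an estimated correlation) but not without db/m replicate 3 (adjusted p = 0.088) or with total counts only (adjusted p = 0.18), where its median turned from 0.22 to -0.04. The members called fell to 2 when db/m replicate 2, db/m replicate 3 or any of the db/db libraries was left out, and came to 12 without db/m replicate 1.

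**Figure D2:**
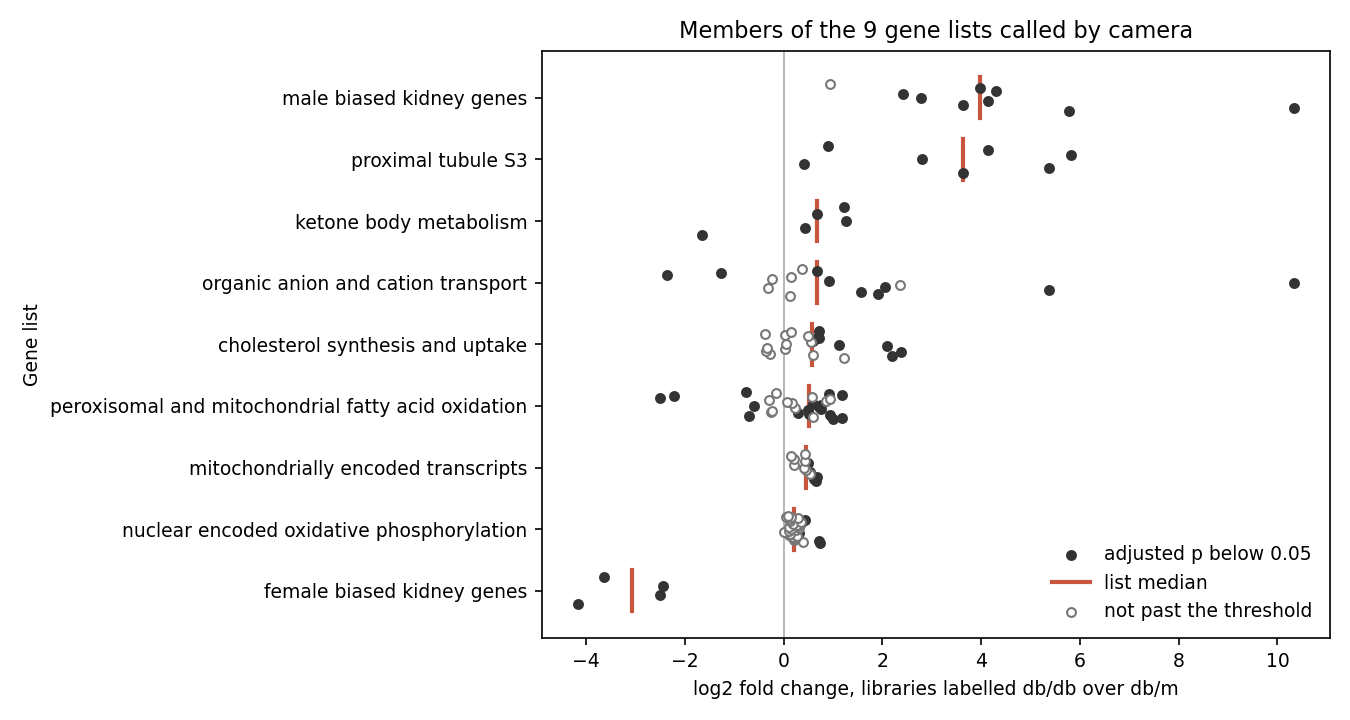
Log2 fold changes of every tested member of the 9 gene lists that passed camera with its preset correlation, with filled points past an adjusted p of 0.05 and a bar at each list median. The male-biased and S3 medians were 3.97 and 3.63, the female-biased median was -3.07, and the nuclear oxidative phosphorylation median was 0.22.

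In all, camera called 8 lists higher and 1 lower of 48 tested, and none with an estimated correlation, where the smallest adjusted p was 0.078 and 5 lists had an unadjusted p below 0.05. By fry, which tests each list against no change rather than against other genes, 11 lists shifted on balance in one direction and 32 held members that changed in either direction. The preset correlation called at least as many lists between other divisions of the 6 libraries, with 8 to 16 in one direction and 2 to 13 in the other. The male-biased, S3, organic ion transport, female-biased and ketone body lists had their smallest p of all 10 divisions in the real one, and the cholesterol, fatty acid oxidation and both mitochondrial lists did not. Even so, the male-biased list was also called in 9 other divisions and the S3 list in 6. The organic ion transport and female-biased lists were each called in 3 others and the ketone body list in 0.

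Outside the lists, the 12 largest rises also included Sec14l3, Ctxn3, Mettl7a3, Mettl7a2, Ces1g, Slc22a26, Akr1c18 and Ugt2b37. Their log2 fold changes ran from 4.55 for Ugt2b37 (SE 0.55) to 7.90 for Sec14l3 (SE 0.71), and several were near the floor under the db/m label, with Sec14l3 at 0.0675 ± 0.117 CPM and Ctxn3 at 0.0468 ± 0.0409 CPM. All db/m counts for Sec14l3 were in db/m replicate 2, and without it the libraries labelled db/m were at 0, so no fold is given. Other folds moved as well, Ces1g from 5.94 to 7.29 without db/m replicate 1 and 5.27 without db/m replicate 2, Ugt2b37 to 5.57 without db/m replicate 3, and Akr1c18 from 5.23 to 5.98 without db/m replicate 2. The 12 largest falls were led by Tm4sf5, a tetraspanin-like membrane protein gene, with 3 counts over the libraries labelled db/db and 4228 over those labelled db/m, a ratio of 1114 (95% exact counting interval 381 to 5406). Its log2 fold change was -9.99 (SE 0.50). All 3 counts were in db/db replicate 1, and without it the libraries labelled db/db were at 0, so no fold is given. Ugt1a2, a glucuronosyltransferase gene, was at 2.71 ± 2.43 against 934 ± 491 CPM, with a log2 fold change of -8.43 (SE 0.95) that became -9.26 without db/db replicate 1, and Ugt1a1 had -4.02 (SE 0.75), or -3.17 without db/m replicate 1. Bhmt, which remethylates homocysteine with betaine, was at 2.59 ± 0.661 against 79.7 ± 45.0 CPM. Aldh1a1, a retinaldehyde dehydrogenase gene, was at 11.7 ± 4.81 against 208 ± 39.7 CPM and Gc, which encodes vitamin D binding protein, at 16.9 ± 2.91 against 250 ± 55.5 CPM. Greb1, Pianp, Sycn, Slc7a12, the ribosomal pseudogene Rps18-ps4 and H2-DMb2 completed the falls. H2-DMb2 had a log2 fold change of -4.86 (SE 1.22, adjusted p = 0.0277), with 137 and 43.1 CPM in db/m replicates 2 and 3 and 2.62 CPM in db/m replicate 1, against 1.90 to 2.33 CPM under the db/db label. Its ratio to H2-DMb1 was 0.97 ± 0.04 under the db/m label and 0.17 ± 0.03 under the db/db label. The call on H2-DMb2 ended with limma-voom (adjusted p = 0.297) and without db/m replicate 2 (log2 fold change -3.44, adjusted p = 0.0617) or any of the db/db libraries (adjusted p = 0.0874 to 0.0966). Members of the Ugt1a, Ces1, Cyp4a, Slc22a and Mettl7a families, H2 genes and pseudogenes share sequence with near copies, so their separate counts are uncertain.

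A few genes linked to tubular injury and complement were lower under the db/db label. Of 17 tested injury markers 1 rose and 2 fell, also over the list alone, and the list did not pass camera (adjusted p = 0.0655). It passed as lower without the filter (adjusted p = 0.0229) and without db/m replicate 1 (0.000733), db/m replicate 2 (0.0496), db/db replicate 1 (0.0389) or db/db replicate 3 (0.0285). Spp1, which encodes osteopontin, had a log2 fold change of -1.61 (SE 0.24, adjusted p = 0.00434) and Cp, which encodes ceruloplasmin, had -1.55 (SE 0.18, adjusted p = 0.00182). Of 14 complement genes 2 rose and 3 fell, or 2 and 4 over the list alone (camera adjusted p = 0.416, and 0.0043 as lower without db/m replicate 1). C3, the central complement component, was at 13.5 ± 3.21 against 198 ± 69.8 CPM, C4b had a log2 fold change of -3.26 (SE 0.52), and Cd55, a complement regulator, had 1.54 (SE 0.12). Within the db/m label, C3, C4b and Spp1 were lowest in db/m replicate 1 (119, 21.6 and 1085 CPM), as was the MHC class II list below. Of 26 collagen and matrix genes 6 rose and 2 fell, or 9 and 3 over the list alone, with Col5a2 higher by 2.44 (SE 0.26). That list did not pass camera (adjusted p = 0.0693) but did without db/m replicate 3 (adjusted p = 7.25e-05), db/db replicate 2 (adjusted p = 0.0388) or db/db replicate 3 (adjusted p = 0.0116), with total counts only (adjusted p = 0.0238) and without the filter (adjusted p = 0.0199), and without both db/m replicate 3 and db/db replicate 3 (adjusted p = 2.12e-08).

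Some markers of the distal nephron and the glomerulus changed, and none of their lists passed camera in the edgeR comparison of all 6 libraries with filter and TMM scaling. In the distal convoluted and connecting tubule list, 4 of 9 fell and 1 rose, or 6 and 1 over the list alone (camera adjusted p = 0.0504). This list passed as lower with DESeq2 size factors (adjusted p = 0.0494), without the filter (0.0199) and without db/m replicate 1 (0.0242), db/m replicate 2 (0.0496), db/m replicate 3 (0.00629) or db/db replicate 2 (0.019). Pvalb, a calcium-binding protein of the distal convoluted tubule, was at 20.7 ± 1.34 against 114 ± 32.2 CPM, and Klk1, tissue kallikrein, was higher by 1.02 (SE 0.13). Of 8 principal cell markers of the collecting duct 2 fell, also over the list alone (camera adjusted p = 0.218, and 0.0175 as lower without db/m replicate 1), including the water channel Aqp2 at 338 ± 82.3 against 721 ± 171 CPM. Of 13 podocyte markers 2 rose and 4 fell, or 3 and 6 over the list alone (camera adjusted p = 0.289). Cdkn1c, a cell cycle inhibitor gene, had a log2 fold change of -1.37 (SE 0.23), and Col4a3, a chain of basement membrane collagen, had 0.71 (SE 0.10). Of 8 glucose transporters 3 fell, also over the list alone (camera adjusted p = 0.0674, and as lower 0.0418 with limma-voom, 0.0303 without the filter and 0.0381 without db/m replicate 2), with Slc5a10, a sodium-coupled mannose and fructose transporter gene, at 233 ± 18.2 against 405 ± 43.5 CPM. Of 8 markers of the thick ascending limb 1 fell, or 0 over the list alone (camera adjusted p = 0.523), and Umod, which encodes uromodulin, had 0.25 (SE 0.25, adjusted p = 0.494). Of 11 intercalated cell markers 1 rose and 2 fell, also over the list alone (camera adjusted p = 0.961). Among 14 endothelial markers, and among 12 of mesangium, pericytes, smooth muscle and fibroblasts, edgeR called none in either direction. DESeq2 called 2 and 1 of them higher, as did an unadjusted p below 0.05, and camera gave adjusted p = 0.333 and 0.773. The endothelial list passed as higher without both db/m replicate 3 and db/db replicate 3 (adjusted p = 0.0103).

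The MHC class II and interferon-stimulated lists varied widely among the libraries labelled db/m. The summed CPM of the MHC class II list was 5768 in db/m replicate 2, 2372 in db/m replicate 3 and 245 in db/m replicate 1, against 626, 661 and 714 in the libraries labelled db/db. The interferon-stimulated list was at 1575, 403 and 155 CPM in the same db/m libraries and at 201 to 221 CPM under the db/db label. Cd74, the invariant chain of MHC class II, had a log2 fold change of -2.40 (SE 0.89, adjusted p = 0.0898), or -1.43 without db/m replicate 2, and it passed without db/m replicate 1 (-2.93, adjusted p = 0.00246). Among 7 MHC class II genes edgeR called none, DESeq2 called 2 lower and 4 were lower at an unadjusted p below 0.05. Of 21 interferon-stimulated genes 1 fell, or 0 over the list alone, with 4 called by DESeq2 and 9 at an unadjusted p below 0.05. Without db/m replicate 1 both lists passed camera as lower (adjusted p = 1.53e-08 and 8.34e-07), against 0.229 and 0.0674 with all libraries. The interferon list also passed without the filter (adjusted p = 0.026). Of 14 macrophage and monocyte markers 3 fell, also over the list alone (camera adjusted p = 0.412, and 0.00032 as lower without db/m replicate 1), and of 9 T and NK cell markers 1 fell, or 0 over the list alone (adjusted p = 0.292, and 0.00141 as lower without db/m replicate 1). Of 4 B and plasma cell markers 1 fell, also over the list alone (adjusted p = 0.255). This was Jchain, the joining chain of antibodies, at 1.97 ± 0.725 against 26.7 ± 20.4 CPM, with a log2 fold change of -3.75 (SE 0.64) that became -2.96 without db/m replicate 1 and did not pass with limma-voom (adjusted p = 0.0577). The neutrophil list summed to 43.5 CPM in db/m replicate 1 and to 4.10 CPM or less in the other libraries (camera adjusted p = 0.37).

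**Figure D3:**
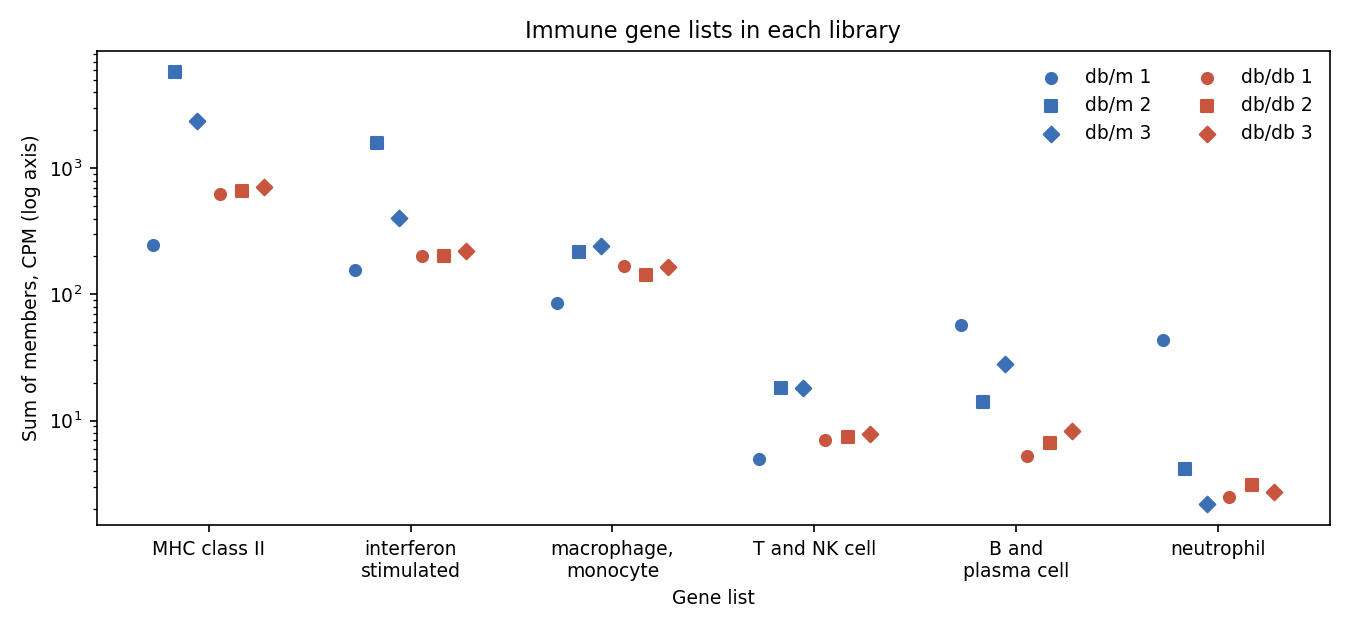
Summed TMM-normalised CPM of the members of 6 immune gene lists in each library, on a log axis, with colour for the label and shape for the replicate. The MHC class II list spanned 245 to 5768 CPM among the libraries labelled db/m and 626 to 714 CPM among those labelled db/db.

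Markers of tissues next to the kidney also varied between libraries. The adipocyte list summed to 250 CPM in db/m replicate 3 and 514 CPM in db/db replicate 3, against 81.8 to 119 CPM elsewhere. Urothelial markers summed to 83.6 CPM in db/m replicate 3 and 1.35 CPM in db/db replicate 2, with 13.6 to 43.2 CPM in the rest. The adrenal list summed to 7.31 to 15.6 CPM under the db/m label and 3.76 to 4.42 CPM under the db/db label, and within it Hsd3b1 was at 8.98, 3.67 and 2.83 CPM in db/m replicates 1 to 3 and 0.317 to 0.522 CPM under the db/db label. Star was at 3.54 to 6.11 CPM under the db/m label and 3.29 to 3.91 CPM under the db/db label. The list members Cyp11b1 and Cyp21a1 had 0 counts in every library, so the sum alone does not show adrenal tissue. Haemoglobin and other red cell genes summed to 280 CPM in db/db replicate 3, 144 CPM in db/m replicate 2 and 29.5 to 85.9 CPM in the others. Skeletal muscle genes stayed at or below 2.04 CPM in sum. Camera gave adjusted p = 0.98 for the adipocyte, 0.246 for the urothelial, 0.0754 for the adrenal and 0.58 for the red cell list. The adrenal list passed as lower without db/m replicate 2 (adjusted p = 0.0496) and the urothelial list without db/db replicate 3 (adjusted p = 0.0356).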

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

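The setting that left out db/m replicate 3 with db/db replicate 3 was chosen after seeing the data. The counts of 2151 higher and 1774 lower genes, 608 and 672 at 2-fold or more, 8 higher lists and 1 lower list stayed within 1.5 times under the settings not named here. Total counts only gave 1072 higher and 4883 lower genes, 1428 of them at least 2-fold lower, with the median of all genes moved to -0.318 by that scaling. The replicate numbers did not pair the libraries (correlations of same-numbered libraries -0.15, 0.06 and 0.14, and not every library correlated best with its own number). With the replicate block the counts were 1313 and 973 genes and 7 lower lists, and lists that gained a call were adrenal gland (0.0331), distal tubule (0.0188), immediate early (0.037), interferon (0.0447), injury (0.0194), unfolded protein response (0.0153) and urothelium (0.037). Leaving out each library in turn gave 1374 to 2011 higher and 851 to 1523 lower genes, 506 to 710 and 436 to 765 at 2-fold or more, 7 to 10 higher lists and 2 to 10 lower lists. Without db/m replicate 3 and db/db replicate 3 there were 1052 higher and 660 lower genes, 414 of them at least 2-fold lower, and 2 lower lists. There the mitochondrially encoded (0.0983), nuclear oxidative phosphorylation (0.0983), ketone body (0.135) and fatty acid oxidation (0.473) lists lost their call, the collagen (2.12e-08), distal tubule (0.031), endothelial (0.0103) and unfolded protein response (0.00073) lists gained one, and 46 named genes lost theirs. Planned settings also ended calls of named genes, 26 with the replicate block, 14 with total counts only and 9 with limma-voom. Leaving out each library in turn ended 14 (db/m replicate 1) to 34 (db/db replicate 3). Lists called lower came to 3 with DESeq2 size factors, 2 with limma-voom and 6 without the filter, and an estimated correlation called 0 higher and 0 lower, with 5 at an unadjusted p below 0.05, while fry, which tests against no change, called 11. Settings that left out libraries had fewer samples, and for the other shifts the cause was not tested. Of the 3925 calls, 55.3% (without db/m replicate 2) to 99.7% (mitochondrial genes left out) were also made in the same direction under the planned settings, 40.0% under the added one, and 0 were called in the opposite direction. Lepr kept its direction and side of the threshold under every setting.

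Among the named genes kept in these repeats, none with a call changed the sign of its fold change. Signs of the other called genes were compared only where both fits called them. No called list changed its camera direction, although the median of the nuclear oxidative phosphorylation list was -0.04 with total counts only. Some named genes and lists with no call did change direction. Ranges are over the fits with libraries left out, and values after "both" are without db/m replicate 3 and db/db replicate 3. Among genes, log2 fold changes with total counts only were -0.09 for Scnn1b, -0.01 for Pck2, -0.08 for Khk and -0.02 for Umod. The ranges were -0.01 to 0.46 for Umod, -0.02 to 0.48 for Slc2a3, -3.27 to 0.09 for S100a8 and -0.45 to 0.10 for Ddit3 (0.08 without db/m replicate 3, and 0.10 for both). Among lists, adjusted p values after a change of direction were 0.971 (DESeq2 size factors), 0.972 (limma-voom), 0.868 (no filter), 0.893 (stricter filter) and 0.946 (replicate block) for adipocyte, 0.754 (total counts only) for chemokines and NF-kB targets, 0.935 (limma-voom) and 0.931 (replicate block) for the intercalated cell, and 0.91 (no filter) and 0.787 (replicate block) for p53 targets. The adjusted p ranges, each with at least 1 change of direction, were 0.103 to 0.931 for adipocyte (both, 0.433), 0.165 to 0.973 for chemokines and NF-kB targets (both, 0.487), 0.393 to 0.95 for gluconeogenesis, 0.359 to 0.942 for glycolysis, 0.545 to 0.977 for insulin and leptin signalling (both, 0.942) and 0.56 to 0.882 for the intercalated cell. They were 0.152 to 0.953 for mesangium, 0.0923 to 0.97 for NRF2, 0.653 to 0.992 for p53, 0.208 to 0.846 for red blood cell (both, 0.772) and 0.248 to 0.935 for TGF-beta (both, 0.822). The cause of these changes was not tested. Depth limits genes of a few counts, such as those near 0.1 CPM.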

Other observations

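Some genes of the circadian clock and of blood pressure control changed, and neither list passed camera. Of 17 circadian clock genes 2 rose and 4 fell, or 3 and 4 adjusted over the list alone, with camera adjusted p = 0.599. Arntl, a core activator of the clock, was at 1.41 ± 0.209 CPM in the libraries labelled db/db and 6.75 ± 1.57 CPM in those labelled db/m (log2 fold change -2.26, SE 0.26, adjusted p = 0.00168, n = 3 each). Cry1, a clock repressor, had -1.26 (SE 0.22) and Dbp, a clock-controlled transcription factor, 1.64 (SE 0.22). The time of day of sampling is not given in the sources used here. Of 12 renin-angiotensin-aldosterone genes 4 rose and 2 fell, or 4 and 3 over the list alone, with a median of -0.07 and a mean of 0.15 (camera adjusted p = 0.715). Ace, which makes angiotensin II, was at 272 ± 39.4 against 54.4 ± 22.9 CPM, and Sgk1, a kinase induced by aldosterone, had -1.29 (SE 0.21). Of 16 NRF2 targets 4 rose and 6 fell, or 5 and 7 over the list alone (camera adjusted p = 0.411). Gsta1, a glutathione transferase gene with near copies, had -3.74 (SE 0.51), or -3.15 without db/m replicate 1, the quinone reductase gene Nqo1 had -0.74 (SE 0.10) and the peroxiredoxin gene Prdx1 0.71 (SE 0.09). Of 15 other antioxidant and ferroptosis genes 5 rose and 2 fell, or 9 and 3 over the list alone (camera adjusted p = 0.111, and as higher 0.0413 without the filter and 0.0279 without db/m replicate 1), with the superoxide dismutase gene Sod1 at 0.98 (SE 0.13). Of 15 hypoxia genes 1 rose and 4 fell, also over the list alone (camera adjusted p = 0.153), among them Car9, a carbonic anhydrase gene induced by hypoxia, at -1.45 (SE 0.13). Of 18 autophagy and lysosome genes 4 rose and 1 fell, also over the list alone, with a median of 0.07 and a mean of -0.16 (camera adjusted p = 0.212). Sqstm1, an autophagy receptor, had 0.94 (SE 0.08).

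Single genes of metabolism and signalling changed, and none of the lists below passed camera in the edgeR comparison of all 6 libraries with filter and TMM scaling. Of 18 unfolded protein response genes 3 rose and 0 fell, in edgeR and over the list alone, and 0 were lower at an unadjusted p below 0.05 (camera adjusted p = 0.0504). This list passed as higher with DESeq2 size factors (0.0494), upper quartile scaling (0.0492), total counts only (0.0433), limma-voom (0.0188) and no filter (0.0108), and without db/m replicate 2 (0.033), db/m replicate 3 (0.00151), db/db replicate 2 (0.00789) or db/db replicate 3 (0.0411). Chac1, which degrades glutathione, had a log2 fold change of 3.89 (SE 0.60), or 5.02 without db/m replicate 3. Of 13 immediate early genes 3 fell, also over the list alone (camera adjusted p = 0.0504). That list passed as lower with DESeq2 size factors (0.0494), without the filter (0.0229) and without db/m replicate 1 (0.00162), db/m replicate 2 (0.00394) or db/db replicate 1 (0.00404). Of 15 genes of branched chain amino acid breakdown 3 rose and 2 fell, or 5 and 2 over the list alone (camera adjusted p = 0.203), with the dehydrogenase gene Ivd at 0.59 (SE 0.08). Of 14 fatty acid synthesis genes 2 rose and 1 fell, also over the list alone (camera adjusted p = 0.335), with Me1, which supplies NADPH, at 574 ± 24.4 against 142 ± 30.9 CPM and the elongase gene Elovl6 at -1.03 (SE 0.17). Of 16 glycolysis genes 2 rose and 5 fell, also over the list alone, with a median of 0.02 and a mean of -0.08 (camera adjusted p = 0.734). Of 12 gluconeogenesis and fructose genes 1 rose and 1 fell, also over the list alone (camera adjusted p = 0.743), the pyruvate carboxylase gene Pcx at 0.72 (SE 0.11) and the fructose transporter gene Slc2a5 at -0.53 (SE 0.10). Of 17 insulin and leptin signalling genes 2 rose and 1 fell (camera adjusted p = 0.821), with Igfbp3, a carrier of insulin-like growth factors, at 1.42 (SE 0.22). Of 15 p53 targets 2 rose and 1 fell (camera adjusted p = 0.961), with the autophagy-linked Trp53inp1 at 0.97 (SE 0.11). Of 16 TGF-beta genes 1 fell (camera adjusted p = 0.47), the signal transducer Smad3 at -0.83 (SE 0.10). Of 20 chemokines and NF-kB targets 1 rose (camera adjusted p = 0.715), the macrophage growth factor Il34 at 2.29 (SE 0.29), and of 18 proliferation genes 1 rose and 1 fell (camera adjusted p = 0.37). In the last 5 lists the counts over the list alone were the same.

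The first pattern is the rise of male-biased and the fall of female-biased kidney genes in the libraries labelled db/db, and all of its tests were chosen after the result was seen. Animals of both sexes are argued against by Xist, at most 0.335 CPM of total counts in any library, and by Y-linked genes that differed by at most 0.18 on the log2 scale between groups. Fewer S3 cells under the db/m label stay open for the male-biased genes, since the 7 S3 markers rose by 0.40 to 5.82 on the log2 scale, neither alike nor with any fall, and other cells may also express them. Exchanged genotype labels cannot be told apart from correct ones: leptin mRNA, which obesity raises in fat, was at 15.6 CPM with 13.6 CPM of Adipoq in db/m replicate 3, a ratio of 1.15, and at 0 counts (at most 0.11 CPM) with 19.2 CPM of Adipoq in db/db replicate 3. Only 1 library per group held at least 5 CPM of Adipoq, the limit set for that ratio. Below it the ratio was 0.649 and 0.55 in db/m replicates 1 and 2 (24 and 11 leptin counts). In db/db replicates 1 and 2 it was 0.308 and 0 (4 and 0 leptin counts). Each library labelled db/m thus had a higher ratio than any labelled db/db, though on few counts outside replicate 3 of each group. The brown fat gene Ucp1 was at 41.2 CPM in db/db replicate 3, and the stock of the animals is not given in the sources used here. An effect of the genotype itself on sex hormone signalling stays open and was not tested.

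The second pattern is the high level of MHC and interferon-inducible genes in db/m replicate 2, where the test on leukocytes was planned before their markers were seen. H2-K1, an MHC class I gene chosen after its values were seen, was at 2219 CPM in this library, against 102 and 283 CPM in the other db/m libraries and 253 to 310 CPM under the db/db label. In db/m replicate 3 the MHC class II list, at 2372 CPM, and B2m, at 694 CPM, were also above every other library but db/m replicate 2. Leukocytes as the whole cause are argued against by 27 leukocyte markers, whose median log2 rise over the other db/m libraries was 0.67 (quartiles 0.11 to 0.81). The median rise was 2.41 for 4 MHC class I genes, which were chosen after values were seen. It was 2.05 (quartiles 1.43 to 2.59) for 21 interferon-stimulated genes, a list fixed before the data were examined. The leukocyte markers include B and plasma cell genes. Of these, Jchain was lower in this library, at 8.78 CPM against 48.9 and 22.5 CPM in db/m replicates 1 and 3. Other explanations stay open, since the labels give these libraries no other difference.

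The third pattern is genes present in all 3 libraries of 1 group and near absent from the other, where the test on strand was planned before the result and the test on pseudogenes was chosen after it was seen. Different handling of strand is argued against by 77 antisense transcripts with a median log2 fold change of -0.059 (quartiles -0.36 to 0.39), against -0.057 for all genes, a set narrowed after a first look to those whose parent symbol was in the table. Different alignment or counting cannot be told apart from other causes. Of the tested ribosomal protein pseudogenes, 14.3% (2 of 14) were called at 4-fold or more, between the bounds of 10% and 25%. Rps18-ps4, named above among the largest falls, is counted in that share and belongs to the pattern itself. It was at 0.372 CPM under the db/db label and 154 CPM under the db/m label. The share is therefore not independent of the pattern and cannot decide. A difference in genetic background stays open and was not tested, and it would be confounded with the genotype for every gene in the report.

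The 6 libraries can be divided into 3 and 3 in 10 ways, and these counts were planned before the result was seen. The real division gave 2151 higher, 1774 lower, 608 at least 2-fold higher and 672 at least 2-fold lower genes, and 1 of 10 divisions, the real one, reached each count, with 0 genes called in any other (142 to 769 at an unadjusted p below 0.05, against 6368). For the 8 lists called higher and the 1 called lower, 10 of 10 divisions gave as many, with up to 16 and 13. With 10 divisions no share under 0.05 can be reached.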
